A study of Rattus norvegicus with 2 samples.

How the data were processed

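Gene expression was measured in bone marrow-derived stromal cells of normal Sprague-Dawley rats (control, 1 array) and of double transgenic rats carrying 2 human transgenes of the renin-angiotensin system (transgenic, 1 array). Per the labels' protocols, cells seeded at 150000 per well of a 6-well plate were kept below confluency, lysed in Trizol, and their RNA was treated with DNase and labelled with Cy3. How many animals or cultures stood behind each array is not given in the sources used here. With 1 array per group no spread between animals or cultures could be estimated, no test between groups was made and no p-value is given.

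The deposited scanner files hold the intensity of each of 62976 spots on a linear scale. Per the file headers they were made with Agilent Feature Extraction 11.0.1.1, which subtracted background and corrected spatial trends but did not normalize between arrays. Flags for outlier, saturated and background spots were deposited with them. Per the file headers both arrays lay on 1 slide and were read in 1 scan, so no slide or scan batch separated the groups. The authors' processed values were deposited as a second table on a log2 scale, with 23153 of the 30367 probes. The normalization behind it is not given in the sources used here, and its centring stays unknown. Its columns had medians of 7.20 in control and 7.18 in transgenic. Over probes above background on both arrays its differences correlated with those computed here at r = 0.978 with a slope of 0.815, in the same direction. That table served as an alternative only.

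From the 58717 non-control spots of each array, those flagged as outliers (446 in control, 505 in transgenic) were left out, and log2 processed signals of repeated spots were averaged per probe. Probes had 1 spot (13137 probes), 2 spots (15840) or 10 spots (1390). Each array's 75th percentile over probes was subtracted. A difference is transgenic minus control on this scale. A probe counted as well above background when over 50% of its spots were. The scanner files carry no gene names, so probes were named by matching their accessions, without versions, to a RefSeq gene table of the rat assembly GRCr8. In this way 18005 of 30367 probes received 1 gene symbol, for 15168 genes, and 12362 probes kept their own identifier. The arrays were designed on an older build, so no coordinates are given. The probe with the highest mean signal stood for a gene. Of 1490 genes with several probes above background, the differences of probes correlated at r = 0.845. Among 302 such genes past 2-fold on the main probe, 283 (93.7%) had the same sign on another probe. There 207 were also past 2-fold in the same direction, and 3 had opposite 2-fold differences (Coa5, Haus3 and RT1-CE5). A gene above background on 1 array only was given a lower bound of the fold, against the higher of the dim probe's own signal and the lowest signal among probes well above background (15.3 units in control, 15.9 in transgenic).

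A size rule of 2-fold took the place of a test. For each of 32 gene lists, the median difference of the members above background on both arrays was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above 97.5. These percentiles describe the 2 arrays and ignore correlation between genes. About 1 list in 20 would stand apart if its genes were drawn at random. Lists of genes that vary together would do so more often, to an extent not measured here. Lists with fewer than 5 measured members were given values only. Of the 32 lists, 11 stood apart on the high side, 8 on the low side, 8 did not and 5 were below the minimum, among them the Y-linked list, whose 1 matched gene, Ddx3, lies on chromosome 13. The lists, the size rule, the rule for named genes and all alternatives not called added were fixed before the data were examined.

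Named genes were the 15 with the largest and the 15 with the smallest difference among symbols above background on both arrays with no outlier flag and no other probe of opposite sign, the 5 with the largest bound in each direction, the renin-angiotensin genes, and up to 4 members of each other list by absolute difference. Members of other-cell lists that were abundant or below background were also open to naming. The values of some genes that this rule takes are not reported here, though list counts and medians include them. Genes named beyond this rule were chosen after their values were seen. These are Il6, Il1a, Tnf, Cxcl10, Mmp3, Mmp9, Mmp10, Mmp13, Adamts4, Pparg, Fabp4, Adipoq, Cnn1, Lum, Fbln1, Thy1, Cd44, Cd14, Fcgr2b, Cd68, Cdk1, Nox4, RT1-CE5, C1qc, Cfd, Plau, Cd36 and Egr3, and the members of added lists.

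Alternatives were median, quantile and loess scaling, normexp background correction with an offset of 50 (limma), the authors' processed values, other filters on dim probes, the mean over a gene's probes, omission of genes with outlier spots, other size rules and another detection flag. Normexp had been planned on the mean spot signal and was run on the median spot signal, the column at hand. Scaling on E1A spike-in probes, and medians of 3 lists without their 3 most extreme members, were added after the data were seen. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1. The size rule was tested on simulated data, in which 200 genes of the control array were changed and the software's spot error was added. It recovered 99% of genes changed by 1.5 log2 and 100% of those changed by 2.5 log2, and called 0.050% of 16084 unchanged genes, for technical error alone. The simulated array kept the control array's detection calls, so genes that fall below background when lowered were not covered. Among the differences of the 15502 measured genes, 4.75% of random lists of 15 genes stood apart without an added shift. The percentile limits fix that share by construction, and it does not hold for genes that vary together. With a shift of 0.5 log2 56% stood apart, and 99% with 1.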

Results

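Bone marrow-derived stromal cells, the adherent non-blood cells that grow out of marrow in culture, were compared between normal Sprague-Dawley rats and double transgenic rats of the same background that carry 2 human transgenes of the renin-angiotensin system. Total RNA from cells seeded at 150000 per well of a 6-well plate and grown to subconfluency was hybridised to 1-colour rat expression arrays. The control group and the transgenic group had 1 array each, so no difference below has a replicate check or a p-value, and every value describes these 2 arrays. Of 30367 probes, 18284 (60.2%) were well above background on the control array and 18456 (60.8%) on the transgenic array. The 75th percentile of probe signal was 905 and 1080 units, and no spot was saturated. Only technical error could be measured. Repeated spots of a probe had a median standard deviation of 0.056 log2 on the control array and 0.055 log2 on the transgenic array, and the scanner software's own error of a difference between arrays had a median of 0.20 log2.

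The comparison asked how gene expression differed with the transgenes. Genes of inflammatory signalling were among those with the largest differences. Ccl20 and Cxcl1, chemokines that attract lymphocytes and neutrophils, were 1465-fold and 1320-fold higher in the transgenic array, and Csf3, which encodes the granulocyte growth factor G-CSF, was 559-fold higher. Hp, the acute phase protein haptoglobin, was 612-fold higher, and Ptges, which makes prostaglandin E, was 602-fold higher. Il1rn, the antagonist of the interleukin-1 receptor, was 178-fold higher. Ramp3, a partner of adrenomedullin and calcitonin-type receptors, was 139-fold higher, while its relative Ramp1 was 98.1-fold lower. The other genes at the top of the ranking were Angptl4 (133-fold), Cited1 (125-fold), Cyp7b1 (115-fold), Egln3 (103-fold), Upp1 (87.7-fold), Scgb1c1 (87.5-fold), the metallothionein Mt2A (85.5-fold) and Pla2g7 (72.6-fold).

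Among the genes with the largest differences in the other direction, Eln, which encodes elastin, was 877-fold lower in the transgenic array, with signals of 27976 units in control and 38.1 in transgenic. Genes of muscle contraction were on this side too. Pln, the phospholamban that regulates the calcium pump of muscle, was 74.1-fold lower, the smooth muscle actin Actg2 was 59.3-fold lower, and the myosin heavy chains Myh1 and Myh8 were 52.1-fold and 46.8-fold lower. Lyz2, a lysozyme abundant in macrophages, was 151-fold lower. Osr1, a transcription factor of mesenchyme, was 178-fold lower, and Ogn, a small matrix proteoglycan, was 89.0-fold lower. Nkain4 (327-fold), Scg2 (221-fold), Gldn (189-fold), Plac9 (189-fold), Itgbl1 (67.2-fold) and Gng13 (54.4-fold) completed the list.

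In all, 15502 genes or unmatched transcripts were well above background on both arrays. The arrays correlated across these genes, which are not independent replicates, with r = 0.949. By the 2-fold size rule 1628 (10.5%) were higher and 1590 (10.3%) lower in the transgenic array, and 12284 lay within 2-fold. At least 8-fold differences were found for 169 and 130 genes, and at least 32-fold differences for 39 and 23. The balance of higher and lower genes rested on the scaling. With the arrays scaled on their E1A spike-in probes, an alternative chosen after the data were seen, the median gene moved up by 1.11 log2, 8110 genes were higher and 332 lower, and higher genes made up 96.1% of those past the size rule in place of 50.6%. Differences below are therefore relative to the bulk of genes on each array.

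**Figure D1:**
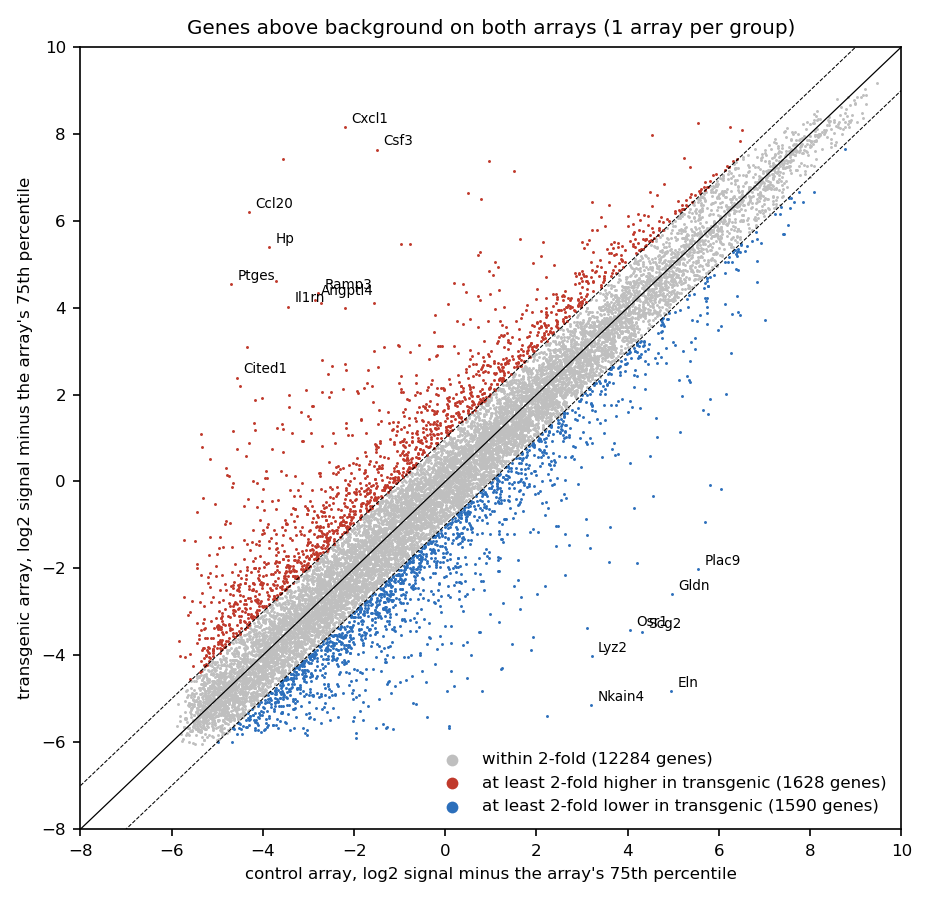
Log2 signal of each of the 15502 genes above background on both arrays, minus its array's 75th percentile, in control (x axis) and transgenic (y axis), with 1 array per group. The solid line marks equal values and the dashed lines 2-fold differences. Red points are the 1628 genes at least 2-fold higher and blue points the 1590 at least 2-fold lower in the transgenic array, and the most extreme named genes are labelled, from Ccl20 (1465-fold higher) to Eln (877-fold lower).

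Further genes were well above background on 1 array only, which gives a lower bound of the fold. They numbered 929 on the transgenic array alone and 778 on the control array alone. With a bound of at least 2-fold there were 429 on the transgenic array alone and 490 on the control array alone. The counts with this bound rested on background and scaling, with 168 and 214 under normexp background correction and 914 and 214 with spike-in scaling. Lcn2, the iron-binding protein lipocalin 2, was at least 12004-fold higher in the transgenic array, and Slpi, a secreted protease inhibitor, at least 10164-fold higher. Dcn, the matrix proteoglycan decorin, was at least 4944-fold higher, complement C3 at least 3663-fold and the chemokine Cxcl2 at least 2342-fold. In the other direction Mall was at least 146-fold lower, Ifgga2l1 at least 101-fold and C1qa, a subunit of complement C1q, at least 99.4-fold lower in the transgenic array. Fxyd1 and Rgs17 were 289-fold and 124-fold lower. Their own dim signals (19.4 and 18.0 units) exceeded the lowest detected signal. These folds are therefore measured ratios, with a spot error of 0.36 and 0.41 log2, and the true folds may be smaller.

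The rat's own renin-angiotensin genes did not stand apart as a group. Their median difference was 0.23 log2 over 12 measured genes, at percentile 89.6 of random lists, with 2 genes at least 2-fold higher and 1 lower. Agtr1a, the type 1a angiotensin receptor, was well above background in the transgenic array only, at least 28.6-fold higher. Enpep, the aminopeptidase that cleaves angiotensin II, was 3.65-fold higher and Igf2r 2.14-fold higher, while Mme, the peptidase neprilysin, was 2.96-fold lower. Within 2-fold were Agtrap (0.81 log2), Prep (0.68), Ctsd (0.60), Atp6ap2 (0.41), Prcp (0.05), Thop1 (-0.14), Ace (-0.27) and Anpep (-0.61). Agt, Agtr1b, Agtr2, Mas1 and Cma1 were not well above background on either array. The human transgenes were not measured, since the probes were designed for rat transcripts. Only in the brighter part of the genes did this list pass the percentile limit, with a median of 0.64.

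Among lists with at least 5 measured genes, the cytokine and the NF-kappaB lists had the 2 highest medians, and the complement and protease lists lay above the random range as well. Of 16 measured cytokines and chemokines, 12 were at least 2-fold higher and 1 lower, with a median of 3.42 log2 (percentile 100), and 6 more were above background in the transgenic array only. Besides Ccl20, Cxcl1 and Csf3, the chemokine Ccl7 was 5.64 log2 higher, Il6 was 23.6-fold higher and Il1a, detected in transgenic only, at least 1062-fold higher. Tnf differed by -0.45 log2, and the interferon-induced chemokine Cxcl10 was 7.40-fold lower. Of 11 NF-kappaB response genes, 7 were higher and 0 lower (median 2.36 log2, percentile 100), among them Nos2 (30.9-fold), Ptgs2 (26.6-fold), Sod2 (22.7-fold) and Bcl3 (13.5-fold), and 4 more were detected in transgenic only. Complement genes had a median of 0.91 log2 (percentile 99.9), with 6 of 12 higher, such as Cd55 (21.6-fold), C1s (15.3-fold) and Serping1 (6.35-fold), and 1 lower, C1qb (5.96-fold). C3 was detected in transgenic only, and C1qa, C1qc and Cfd in control only. Matrix metalloproteinases and ADAMTS proteases had a median of 1.19 log2 (percentile 99.98), with 7 of 11 higher and 3 lower. Mmp2 was 6.55-fold and Adamts1 5.87-fold higher, Mmp16 6.79-fold and Mmp12 4.84-fold lower, and Mmp3, Mmp9, Mmp10, Mmp13 and Adamts4 were detected in transgenic only, with bounds from at least 2.99-fold (Adamts4) to at least 539-fold (Mmp3). Plau was detected in control only.

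Interferon-stimulated genes went the other way. Of 26 measured, 19 were at least 2-fold lower in the transgenic array and 0 higher, with a median of -1.70 log2 (percentile 0). Bst2, which tethers virus particles, was 21.2-fold lower, the ubiquitin-like Isg15 16.3-fold, Rsad2 10.7-fold and Ifit2 10.3-fold lower. Major histocompatibility complex genes did not stand apart (median 0.21 log2, percentile 91.1), with 4 of 16 higher and 2 lower. The class II chaperone Cd74 was 4.98-fold lower and RT1-Db1 3.23-fold lower, whereas the class I genes RT1-CE10 and RT1-A2 were 10.2-fold and 3.73-fold higher. Class I genes have near-identical copies and their values are uncertain. The probes of RT1-CE5 gave 1.35 and -2.72 log2. In the brighter part of the genes this list had a median of 0.92 and passed the percentile limit.

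Genes of hypoxia and glycolysis were higher as a group. Of 23 measured, 18 were at least 2-fold higher and 0 lower, with a median of 1.56 log2 (percentile 100). Egln3, an oxygen-sensing prolyl hydroxylase, was 103-fold higher, Ddit4 9.05-fold, the glucose transporter Slc2a1 8.60-fold and the kinase Pdk1, which inhibits pyruvate dehydrogenase, 6.68-fold higher. Adipocyte genes had a median of 1.75 log2 (percentile 100), with 7 of 11 higher and 2 lower. Angptl4, an inhibitor of lipoprotein lipase, Lpl (31.0-fold), the lipase itself, and Cebpd (6.87-fold) were higher, while Cebpa and Pparg, transcription factors that drive fat cell differentiation, were 6.81-fold and 6.76-fold lower, and Fabp4 and Adipoq were not well above background on either array. Cd36 and Cfd were detected in control only. Immediate early genes had a median of 0.84 log2 (percentile 100), with 8 of 22 higher and 2 lower, led by Nr4a2 (11.8-fold), Btg2 (4.88-fold), Myc (4.08-fold) and Nr4a3 (3.29-fold), and Egr3 was detected in control only. Unfolded protein and heat shock genes had a median of 0.64 log2 (percentile 99.98), with 6 of 21 higher and 1 lower. Dnajb9 was 5.02-fold, Trib3 3.64-fold, Pdia4 2.57-fold and Calr 2.48-fold higher.

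Growth and angiogenic factors had a median of 0.46 log2 (percentile 99.8), with 11 of 26 higher and 4 lower. Angpt1, a ligand of endothelial Tie2, was 50.9-fold higher, Cxcl12 8.55-fold (5.79 log2 on another probe) and Areg 6.83-fold higher, and Bmp3 12.2-fold lower. In addition, 2 more genes were detected in transgenic only and 1 in control only. In the brighter part of the genes the list's median was 0.18 and it no longer passed the limit. Vasoactive and steroid receptor genes had a median of 0.57 log2 (percentile 99.7), with 4 of 15 higher and 4 lower. The vasodilator peptide Adm was 70.3-fold, the endothelin receptor Ednrb 56.4-fold, Ptgs1 15.6-fold and Hsd11b1, which regenerates active glucocorticoid, 12.9-fold higher. This group fell inside the random range with normexp background correction (median 0.12) and with the authors' processed values (median 0.28).

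Genes of matrix, bone and contraction were lower relative to the other genes. Of 18 smooth muscle and contractile genes, 9 were at least 2-fold lower and 0 higher, with a median of -1.06 log2 (percentile 0) that became 0.054 with spike-in scaling. Actg2 was 59.3-fold, the smooth muscle myosin Myh11 15.1-fold, Acta2 4.14-fold and Vcl 3.43-fold lower, and Cnn1 differed by 0.03 log2. Extracellular matrix and fibrosis genes had a median of -0.83 log2 (percentile 0), with 10 of 25 lower and 0 higher, and 0.29 with spike-in scaling. Eln, Postn (12.3-fold), Fbln5 (6.47-fold) and Col3a1 (5.71-fold) were lower, while Dcn, Lum and Fbln1 were detected in transgenic only. Osteoblast genes had a median of -1.08 log2 (percentile 0), with 7 of 13 lower and 0 higher, and 0.031 with spike-in scaling. Ogn, Omd (29.3-fold), the matrix phosphoprotein Spp1 (18.4-fold) and Postn were lower. Chondrocyte genes had a median of -1.07 log2 (percentile 0.43), with 3 of 6 lower and 0 higher, and 0.039 with spike-in scaling. Acan, the cartilage proteoglycan aggrecan, was 8.76-fold lower, Matn4 4.25-fold and Col9a2 3.59-fold lower, and Col2a1 differed by -0.30 log2, and 2 more genes were detected in transgenic only and 2 in control only.

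Markers used to define mesenchymal stromal cells were mixed. The median was 0.59 log2 (percentile 99.9), with 6 of 17 higher and 4 lower, and with the mean over a gene's probes it was 0.34 and inside the limit. Cxcl12 was 8.55-fold higher on its main probe and 5.79 log2 higher on another. Itga1 was 8.01-fold, Mcam 7.05-fold and Nes 5.91-fold lower. Thy1 and Cd44 differed by 0.61 and 0.25 log2. Skeletal muscle genes did not stand apart (median -0.35 log2, percentile 12.9), with 2 of 15 higher and 5 lower, led by Myh1, Myh8, Tnnt1 (9.39-fold lower) and Actc1 (4.79-fold higher), and passed the limit only without a background filter (-0.39). WNT and BMP signalling genes did not stand apart either (median -0.32 log2, percentile 8.3), with 5 of 18 higher and 6 lower. Wnt5a was 45.2-fold and Sfrp4 5.75-fold higher, and Ccn5 17.5-fold and Id1 6.37-fold lower. Without a background filter this list's median was -0.49 and passed the limit.

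Markers of other cell types that a marrow culture could hold were measured alongside. Monocyte and macrophage markers had a median of -2.53 log2 (percentile 0), with 6 of 10 lower, 3 higher and 4 more detected in control only. Without its 3 most extreme members, a test added after the data were seen that by construction pulls a median towards 0, the list had a median of -0.51 (percentile 10.3) and lost its call. Lyz2 was 151-fold, Tyrobp 46.1-fold, Fcer1g 22.3-fold and Laptm5 7.07-fold lower, while Cd14, Fcgr2b and Cd68 were higher by 1.78, 1.69 and 1.58 log2, and Ptprc and Itgam were not well above background on either array. Neural and glial genes had a median of -0.83 log2 (percentile 0.425), with 4 of 9 lower and 1 higher, and 0.28 with spike-in scaling. Ncam1 (8.03-fold), Nes (5.91-fold) and Uchl1 (3.76-fold) were lower and S100b 2.17-fold higher, and 4 more were detected in transgenic only and 3 in control only. The call was lost when dimmer genes were included (-0.54 with genes above background on 1 array or both, -0.35 without a filter). Erythroid markers did not stand apart (median 0.39 log2, percentile 91.6), with 2 of 5 higher, the globin chaperone Ahsp (18.1-fold) and Hbb-b1 (2.60-fold), and 0 lower. They passed the limit with genes above background on 1 array or both (0.88) and without a filter (0.39). The lymphocyte, granulocyte and mast cell, endothelial and epithelial lists had fewer than 5 measured members. Among these, Cd3d and Gzmb differed by 0.04 and -0.63 log2, the granule peptide Camp was 41.1-fold higher, Erg was 21.0-fold and Flt1 2.13-fold lower, Cdh5 and Sox18 differed by -0.58 and -0.44 log2, Krt7 was 3.57-fold higher, and Krt5, Krt14 and Ocln differed by -0.21, -0.16 and -0.41 log2. Flt1 came to 0.020 log2 with spike-in scaling.

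Cell cycle genes had a median of -0.69 log2 (percentile 0.15), with 7 of 20 lower and 1 higher, and 0.43 with spike-in scaling. Tyms was 3.53-fold, the mitotic kinase Bub1 3.44-fold and Ccnb1 2.79-fold lower, Mcm7 was 2.84-fold higher, and Cdk1 differed by -0.01 log2, and 1 more gene was detected in transgenic only and 2 in control only. In the brighter part of the genes the median was -0.57 and inside the limit. The p53 targets and senescence genes did not stand apart (median -0.29 log2, percentile 12.1), with 2 of 17 higher and 5 lower, led by Igfbp3 (5.75-fold higher), Btg2 (4.88-fold higher), Fas (5.86-fold lower) and Cdkn2a (4.72-fold lower). With genes that had outlier spots left out, that median was -0.46 and passed the limit. NADPH oxidase and antioxidant genes had a median of 0.12 log2 (percentile 85.3), with 4 of 18 higher and 2 lower. The superoxide-producing oxidase Nox1 was 46.2-fold, Sod2 22.7-fold and Xdh 4.31-fold higher, Ncf4 was 3.34-fold lower, and Nox4 was detected in control only, at least 56.1-fold lower. Housekeeping genes had a median of -0.01 log2 (percentile 66.4). The glycolytic Pgk1 was 3.66-fold higher, and the other 18 lay within 2-fold on their main probes, Gapdh at 0.81 and Tuba1b at -0.88 log2 among them. Other Gapdh probes gave 0.67 and 1.13 log2. Of the Y-linked list only 1 of 9 members matched a gene symbol, and that gene lies on chromosome 13, so the list gave no result.

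**Figure D2:**
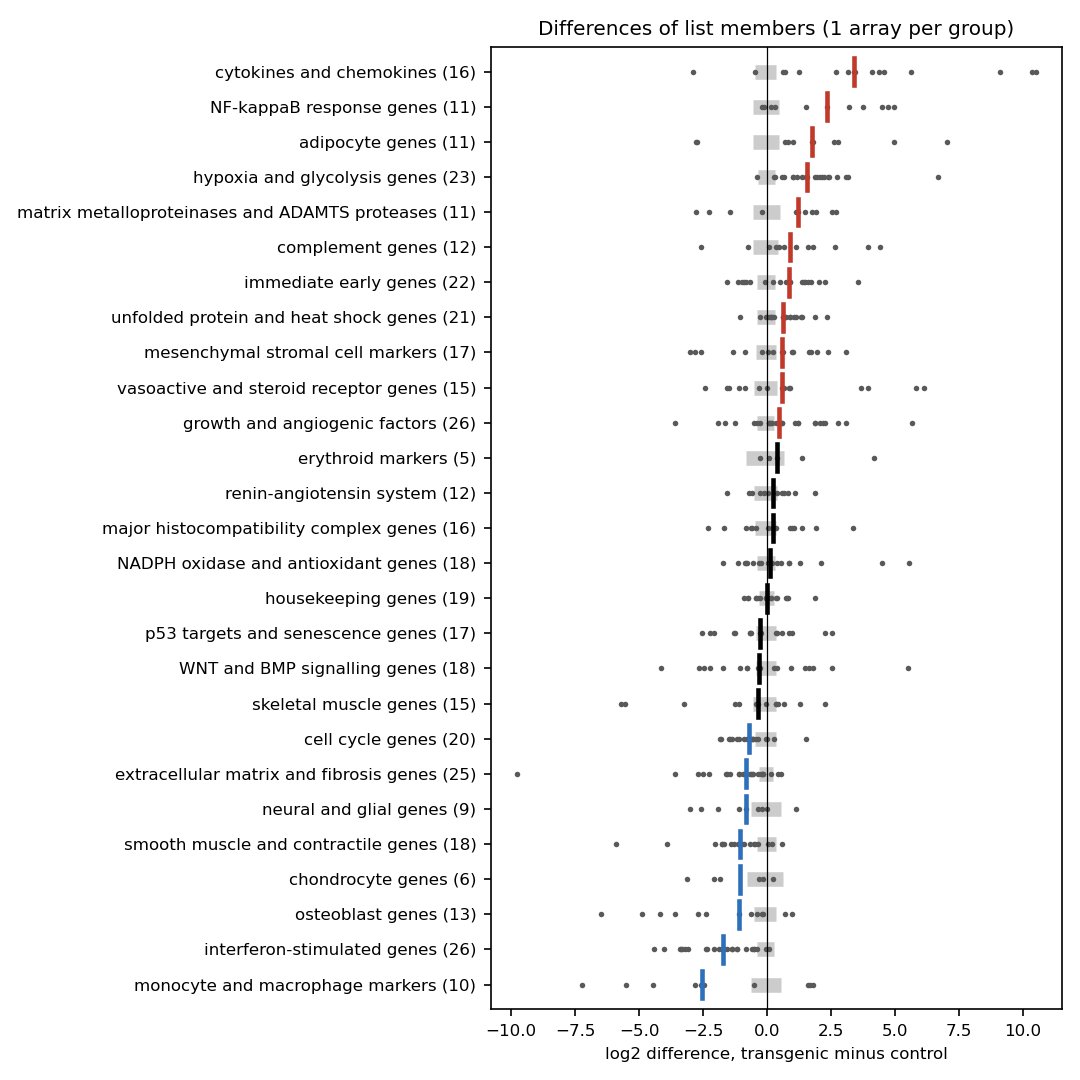
Log2 difference, transgenic minus control, of the members of the 27 gene lists with at least 5 genes above background on both arrays (grey points, 1 array per group), with the number of measured genes after each name. Short vertical lines are list medians, red for 11 lists above and blue for 8 below the central 95% of medians of random lists, shown as grey bars, and medians run from -2.53 (monocyte and macrophage markers) to 3.42 (cytokines and chemokines). With spike-in scaling the osteoblast, chondrocyte, smooth muscle, matrix, cell cycle and neural medians lie above 0.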

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

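Of the arrays' 96 ERCC control probes, which no comparison used, 5 were well above background on both arrays. The probe ERCC-00170_100 was 1.27 log2 higher in the transgenic array than in the control array after scaling, with signals of 220 units in control and 632 in transgenic over 35 spots each. The other 4 differed by 0.07, -0.04, -0.40 and -0.49 log2. The spike-ins with strong signal on these arrays were E1A, whether ERCC RNA was added is not given in the sources used here, and cross-hybridisation of sample RNA was not tested, so the value is not taken as a reading of an external control. This look at the control probes was made after the other results were seen.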

How the results depend on the processing

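The spike-in scaling and the medians without 3 members were tests chosen after the data were seen. No paired analysis was possible because each group had 1 array, and leaving out a replicate was impossible for the same reason. Of 19 lists that stood apart, 14 did so in the same direction under every setting fixed beforehand that gave a value, and the macrophage and chondrocyte lists had too few members for a value in the brighter part of the genes. Median and spike-in scaling shift every gene alike, so by construction neither could move a list across the percentile limit. Of 296 list medians under another setting, these scalings included, 261 kept both their sign and their side of the limit. Another 14, of lists that did not stand apart, changed sign on the same side of the limit. These were 8 of the housekeeping list, whose medians lay near 0 except with spike-in scaling, 2 of the NADPH oxidase list (-0.09 with genes above background on 1 array or both, -0.22 without a filter), 2 of the WNT and BMP list (0.40 in the brighter part, 0.79 with spike-in scaling), and 1 each of the p53 (0.82) and skeletal muscle (0.76) lists with spike-in scaling. The 120 named genes past 2-fold kept their sign under every setting fixed beforehand that gave a value, and 115 stayed past 2-fold with the authors' processed values, which kept the fewest among the scalings fixed beforehand.

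Genes at least 2-fold higher and lower numbered 1628 and 1590. They were 907 and 909 with the authors' processed values, where the share of genes fell too (7.7% of 11819 genes each way, against 10.5% and 10.3% of 15502). That setting changes both the normalization and the genes covered, and the cause was not tested. They were 792 and 599 in the brighter part, with 7751 genes (10.2% and 7.7%), and 2674 and 2899 without a background filter, with 26913 (9.9% and 10.8%). The 1.5-fold rule gave 2954 and 3488 and the 3-fold rule 747 and 638, by construction. Spike-in scaling gave 8110 and 332, through a constant shift of 1.11 log2. Genes above background in transgenic only and in control only (429 and 490) were 168 and 214 with normexp, and 914 and 214 with spike-in scaling. The control-only count was 313 with a 3-fold bound.

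With spike-in scaling the medians of the osteoblast (0.031), chondrocyte (0.039), smooth muscle (0.054), matrix (0.29), cell cycle (0.43) and neural (0.28) lists and the value of Flt1 (0.020) changed sign, while the lists kept their percentiles. In the brighter part of the genes the cell cycle (-0.57) and growth factor (0.18) lists lost their call, and the renin-angiotensin (0.64) and histocompatibility (0.92) lists gained one. The vasoactive list lost it with normexp (0.12) and the authors' values (0.28), and the stromal marker list with the mean over probes (0.34). The neural list lost it with genes above background on 1 array or both (-0.54) and without a filter (-0.35), where the erythroid list gained one (0.88 and 0.39). Without a filter the WNT and BMP (-0.49) and skeletal muscle (-0.39) lists gained one, as did the p53 list without genes that had outlier spots (-0.46). Without its 3 most extreme members, which by construction pulls a median towards 0, the macrophage list (-0.51) lost its call, and the cytokine (3.18) and hypoxia (1.53) lists kept theirs. The cause of the other changes of call was not tested. Dim probes limit the folds of genes near the lowest detected signal of 15.3 and 15.9 units.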

Other observations

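All lists in this part were chosen after the data were seen, except that the second macrophage and second hypoxia lists, the mural cell list and the fibroblast list were written before their own values were looked at, apart from Loxl2, Dcn, Lum, Fbln1, Pdgfra and Sfrp1. The tests of macrophages as a source of cytokine transcripts and of culture differences below were also chosen after the result was seen.

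Genes of prostaglandin synthesis and degradation were higher in the transgenic array, with 8 of 11 measured members at least 2-fold higher, 0 lower and a median of 1.48 log2. Both cyclooxygenases, Ptgs1 (15.6-fold) and Ptgs2 (26.6-fold), the phospholipase Pla2g2a (12.0-fold) and the synthase Ptges (602-fold) were among the higher genes. Ptgr1 (2.78-fold) and Hpgd (2.34-fold) were higher as well, while Tbxas1 was detected in control only, at least 3.08-fold lower. All 8 measured acute phase and metallothionein genes were higher (median 5.24 log2), including Lbp (26.8-fold), Mt1 (53.3-fold) and the zinc transporter Slc39a14 (9.28-fold), and 4 more were detected in transgenic only. Both lists hold genes already seen among the largest differences, such as Ptges, Hp, Il1rn and Mt2A, so they are no test of their groups, and their place among random lists is not given. Genes of the mitochondrial respiratory chain, with ATP synthase and some assembly factors, had a median of -0.36 log2 (percentile 0), but 70 of 77 lay within 2-fold and the median was 0.75 with spike-in scaling. Cytosolic ribosomal protein genes (median -0.036 log2 over 73 genes, percentile 75.04), proteasome genes (-0.27, percentile 3.93), cholesterol synthesis genes (0.15, percentile 84.7) and Hox genes (-0.41, percentile 10.4) did not stand apart. The ribosomal list did so with the authors' processed values (0.11, percentile 99.0, on the high side) and the Hox list with normexp (-0.48, percentile 2.39, on the low side). With spike-in scaling all 4 medians were above 0. The median of the Hox list hid differences in both directions. Of its 8 measured genes, 1 was at least 2-fold higher, Hoxa11 (4.30-fold), and 3 were lower, among them Hoxd13 (2.83-fold). A further 2 were detected in control only, among them Hoxb7 (at least 17.4-fold lower), and 1 in transgenic only. With spike-in scaling 4 of the 8 were higher and 0 lower.

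A list of mural cell genes, those of pericytes and vascular smooth muscle, had a median of -1.04 log2 over 16 measured members (percentile 0), with 9 at least 2-fold lower and 0 higher, and the median turned to 0.072 with spike-in scaling. Crip1 (9.83-fold), Sorbs2 (7.69-fold), Ppp1r14a (6.11-fold) and Cspg4 (5.62-fold) were lower, and Sncg was detected in control only, at least 44.9-fold lower. Pcp4 went the other way, at least 200-fold higher in the transgenic array. A fibroblast list did not stand apart (median -0.28 log2 over 17 genes, percentile 14.6, and 0.83 with spike-in scaling), with 4 higher and 7 lower. Dcn (at least 4944-fold) and Lum (at least 156-fold) were detected in transgenic only, while Ccdc80 and Mfap4 were 9.77-fold and 8.12-fold lower.

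Cytokine, chemokine and NF-kappaB genes were higher in the transgenic array. More macrophages in that culture would bring their abundant transcripts, and the lower Lyz2 (151-fold), Tyrobp (46.1-fold), Fcer1g (22.3-fold) and C1qa (at least 99.4-fold) argue against this. The macrophage list's median of -2.53 log2 does so more weakly, since a second macrophage and leukocyte list had a median of -0.16, and Cd14, Fcgr2b and Cd68 were higher. Without its 3 most extreme members the first list's median was -0.51 and it lost its call, though by construction this removal pulls a median towards 0. Other blood cells were not tested as a source, and some of their markers were higher, among them Camp (41.1-fold), Ahsp (18.1-fold) and Hbb-b1 (2.60-fold). Many others were well above background on neither array. These were 12 of 15 granulocyte and mast cell markers, 11 of 15 lymphocyte markers and 5 of 11 erythroid markers on the array. The choice among these scalings did not account for the pattern, since the lowest median of the cytokine list over 6 other scalings was 2.85 log2, with the authors' processed values. Median and spike-in scaling raise every gene alike, by 0.067 and 1.11 log2, and could not have lowered it. A difference between the cultures unrelated to genotype, such as medium, density or a stimulus in 1 well, cannot be told apart from the transgenes with 1 array per genotype. The hypothesis that the transgenes set off this expression therefore stays open and untested.

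Hypoxia and glycolysis genes were also higher. A few members did not carry the list, since 18 of its 23 measured genes were at least 2-fold higher and 0 lower. A second list of 19 other measured genes, made as the test of this, had a median of 0.96 log2 (percentile 100). Of these, 8 were at least 2-fold higher, such as Higd1a (7.46-fold) and Pgm1 (4.83-fold), and 2 lower. Its genes are not those of the first list, so it shows only that other hypoxia genes were higher as well. The lowest excess of the first list's median over that of housekeeping genes was 1.39 log2 over 6 scalings, with the authors' processed values, although median and spike-in scaling shift every gene alike and could not have altered it. A difference of oxygen or density between the cultures cannot be told apart from genotype with 1 array per genotype.

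Monocyte and macrophage markers were lower in the transgenic array, and fewer macrophages in that culture is a candidate explanation. Of the 20 genes of a second macrophage and leukocyte list above background in control, 8 (40%) were at least 2-fold lower in transgenic, among them Trem2 (at least 63.9-fold) and Coro1a (5.90-fold), under the 80% that this explanation needed and under the 50% set beforehand as arguing against it. With the dim genes taken at their own signals the share was 45%, also under the 50%. It was 45% with median, quantile, loess and spike-in scaling, 30% with normexp and 20% with the authors' processed values. Normexp adds an offset of 50, and the authors' values did not go below 5.65 log2. Both limit how far dim genes can fall, so these lower shares carry no weight against the explanation. Cd48 and Apoe were 1.93-fold and 1.92-fold lower, just short of the size rule. Draws with the scanner software's error, made after the share was seen, ran from 45% to 55% (central 95%). They started from the 45% and not from the 40% that the rule set beforehand gave. Only the 12 genes measured on both arrays were varied, under the main scaling. The draws therefore give no spread for the 40%, and whether it lay below 50% by more than technical error was not settled. The share lay below 80% in all of these, and the explanation stays open. Of the same 20 genes 4 were higher, namely Arhgdib (3.91 log2), Cd53 (2.51 log2), Lgals3 (4.59-fold) and Gpnmb (1.31 log2), and Slc11a1, detected in transgenic only, was at least 4.58-fold higher. The 12 genes measured on both arrays had a median of -0.16 log2 (percentile 36.2, and 0.95 with spike-in scaling), which leaves out 8 detected in control only.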
